A study of Penicillium oxalicum with 18 samples.

How the data were processed

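The data are RNA profiles of mycelium of the filamentous fungus Penicillium oxalicum, from the wild-type strain 114-2 and from a strain with the nag3 gene deleted. Per the labels' protocols, mycelium was first grown for 24 h at 30 °C in a medium with 2% glucose, and was then moved to a second medium for 24 h. The second medium held 1% bran and 1% microcrystalline cellulose (called bran-cellulose here), 2% glucose, or 2% N-acetylglucosamine (GlcNAc, the sugar unit of chitin). The growth protocol names the first 2 of these media, and the sample labels name all 3. The 2 genotypes and 3 media give 6 groups of 3 libraries, 18 in all, and every column of the table was matched to its sample by its name.

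The authors deposited FPKM values (fragments mapped to a gene, scaled by its length and by the mapped fragments of the library) for 9261 gene identifiers, per the file headers, with 2 decimals. Of these identifiers 9226 are PDE_ locus tags and 35 are XLOC_ loci. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. The labels' protocol describes tag libraries cut with NlaIII and MmeI, in which one tag stands for one transcript and no length correction is needed, while the table's header names a unit divided by length. Division by length is the same for 1 gene in every library, but it sets the gene's size relative to the filter and to the offset of 1 FPKM used below, and so its log2 difference. Read counts per library were not used here and the absolute depth is unknown. Low values move in steps of 1 read in part of the table. From these steps the relative depth of 12 of 17 libraries could be set against the remaining one, and the log2 value of 1 read lay between -0.05 and 0.15 relative to it. Some values fell between whole steps, so reads were not recovered and no count test was run.

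The FPKM values were used as deposited, with no further scaling. Genes with at least 1 FPKM in at least 3 libraries were kept, which left 8390 of 9261 and removed 871. The test was limma 3.58.1 in R 4.3.3, two-sided, on log2(FPKM + 1), with 1 mean per group over all 18 libraries and an intensity trend in the prior for the spread. P-values were adjusted by the Benjamini-Hochberg method over the 8390 genes of each comparison. A gene was called at an adjusted p under 0.05 with an absolute log2 difference of at least 1, and "rose" and "fell" are used for called genes. Log2 differences are on the scale of log2(FPKM + 1), which understates the change of low genes. Figures were drawn with matplotlib 3.10.9. A group of 3 against 3 has 10 splits, so an exact permutation test of a single gene could not go below p = 0.1 and was not used.

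The procedure was tested on simulated data with 8390 genes, of which 100 were changed 2-fold and 100 were changed 4-fold. In the simulated bran-cellulose comparison 84% of the 4-fold and 21% of the 2-fold changes were called, with 1 false call among 8190 unchanged genes. In the simulated glucose comparison the shares were 87% and 29% with 4 false calls, and in the simulated GlcNAc comparison 86% and 40% with 5 false calls. A 2-fold change of FPKM lies below the fold threshold on log2(FPKM + 1), most of all for low genes, which holds down its share of calls. By the adjusted p alone, 68%, 71% and 78% of the 2-fold changes were found in these comparisons. The simulated noise was independent between genes and had the same SD in every group. In the real groups the median SD ran from 0.103 to 0.187, so false calls may differ there.

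The comparisons were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. The comparisons were deletion against wild type within each medium and over all 3, bran-cellulose and GlcNAc against glucose within each genotype, and 3 tests of whether the genotype difference itself differed between media, 11 in all. The table does not pair its locus tags with gene names. The reference gene table at hand is of another strain (assembly ASM172317v3) and 0 of the 9261 identifiers matched it, so the 24 gene lists planned as search words could not be formed. What remained were 13 locus tags fixed beforehand, whose names come from published work on strain 114-2 as recalled and not from the deposited data. They fall into 6 lists, none with more than 4 members. Set tests needed 5 members and were not run, and counts per list are given over all genes and adjusted over the list alone.

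The rule for named genes took these 13 tags in every comparison. It added, as nothing pairs identifiers with names, at most 2 identifiers that rose and 2 that fell per comparison, those with the greatest log2 difference among called genes with at least 10 FPKM in the higher group and no overlap between libraries; the condition on overlap was applied where a comparison has 1 group on each side, and not to the comparison over 3 media or to the differences between media. It also took genes called the same way in all 3 media, and genes with at least 5 FPKM in all 9 wild-type libraries and under 1 in all 9 deletion libraries. Other identifiers, and all ranges of consecutive locus tags, were chosen after their values were seen. Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-ratio, quantile and TPM scaling, a fit of only the groups compared, no fold threshold, no trend, array weights, the replicate number as a block, and leaving out each library in turn. The fit of only the groups compared was added for single genes after the data were seen.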

Results

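Transcript levels were measured in 18 libraries of Penicillium oxalicum, a filamentous fungus used as a producer of cellulases, to ask how deletion of nag3 changes expression on an inducing plant substrate (bran-cellulose), on glucose and on GlcNAc. Each of the 6 groups held 3 libraries, and levels below are mean FPKM ± SD with n = 3. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. FPKM sums per library ran from 920824 to 1083828, and between 854 and 955 identifiers were listed at 0. Pearson correlations of log2(FPKM + 1) across genes between replicates lay between 0.952 and 0.986. Between genotypes they were 0.974 to 0.979 on bran-cellulose, 0.849 to 0.9197 on glucose and 0.815 to 0.842 on GlcNAc. No 2 libraries held identical values.

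**Figure D1:**
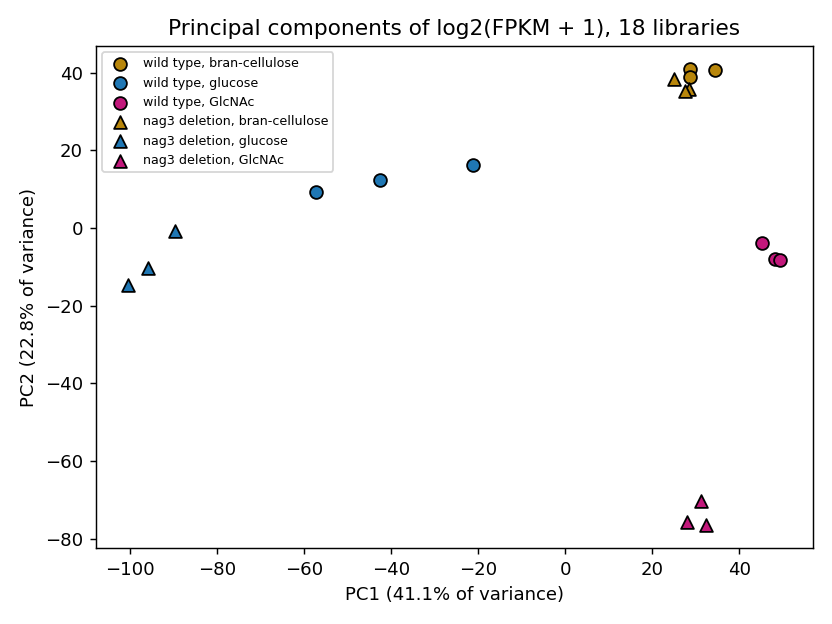
First and second principal components of log2(FPKM + 1), with 41.1% and 22.8% of the variance; each point is a library, circles are wild type, triangles the nag3 deletion, and colours give the medium. The bran-cellulose libraries of both genotypes lie together, and the 3 wild-type glucose libraries spread along the first component from -57.24 to -21.18.

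The table does not name nag3, so its level could not be reported by name. The screen fixed beforehand for a deleted gene, with at least 5 FPKM in all 9 wild-type libraries and under 1 in all 9 deletion libraries, found 0 genes. PDE_00970 came nearest and was chosen after its values were seen: it lay between 2.08 and 4.55 FPKM in the 9 deletion libraries and at 44.8 FPKM or more in the 9 wild-type libraries. Among genes with at least 5 FPKM in all 9 wild-type libraries, 1 passed a looser screen. This was PDE_00970, whose highest deletion library was more than 5 times below its lowest wild-type library.

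On bran-cellulose, few genes differed between the deletion and the wild type, and the major cellulase genes had lower mean levels in the deletion. xyn10A (PDE_08094), a xylanase gene, fell from 33.97 ± 1.19 to 15.69 ± 1.57 FPKM (log2 difference -1.07, SE 0.12, adjusted p = 0.00026). The 4 cellulase genes did not reach the fold threshold with all libraries. The cellobiohydrolase gene cel6A (PDE_07124) was at 630.8 ± 75.5 against 1192 ± 164 (log2 difference -0.91, adjusted p = 0.0151) and the endoglucanase gene cel7B (PDE_07929) at 191.8 ± 12.04 against 307.6 ± 9.996 (-0.68, adjusted p = 0.0104). cel7A-2 (PDE_07945), the gene of the main cellobiohydrolase, was at 1495 ± 140 against 2277 ± 128 (-0.61, adjusted p = 0.400), and the endoglucanase gene cel5B (PDE_09226) at 953.3 ± 99.0 against 1255 ± 131 (-0.40, adjusted p = 0.267). Of these 4, 0 were called, 2 passed the adjusted p at any size, and 4 did so when adjusted over the list alone. Leaving out 1 library at a time, cel6A passed the fold threshold without wild-type replicate 1 (-1.03, adjusted p = 0.0171) but missed the adjusted p in 4 of 6 fits, and cel7B missed it in 3 of 6 (highest adjusted p 0.0946 and 0.0579). In a fit of only these 6 libraries cel7B passed it (adjusted p = 0.0162) and cel6A missed it (0.0790). In that fit the adjusted p was 0.0734 for cel7A-2 and 0.233 for cel5B.

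The remaining tags on bran-cellulose gave no call. The β-glucosidase gene bgl1 (PDE_02736) differed by 0.40 and bgl2 (PDE_00579) by -0.12 on the log2 scale. The regulator genes clrB (PDE_05999, an activator of cellulase genes), xlnR (PDE_07674, an activator of xylanase and cellulase genes), creA (PDE_03168, the carbon catabolite repressor) and amyR (PDE_03964, an activator of amylase genes) differed by -0.20, 0.03, 0.07 and -0.14. The glucoamylase gene amy15A (PDE_01201) differed by -0.12 and brlA (PDE_00087), a central regulator of conidiation, by 0.01. By the naming rule, PDE_00970 (2.30 ± 0.358 against 51.72 ± 2.53) and PDE_00969 (3.97 ± 0.662 against 65.04 ± 4.68) fell, and PDE_06031 (100 ± 14.0 against 18.53 ± 4.41) rose, as did PDE_02978, which was listed at 0 in the wild type. In all, 16 genes rose and 17 fell of 8390 tested, and 605 had an unadjusted p under 0.05. Array weights gave 31 up and 35 down, 66 genes, and without the fold threshold 33 rose and 27 fell, 60 in all. The call of xyn10A ended without deletion bran-cellulose replicate 1 (log2 difference -0.999), and that of PDE_02978 ended in a fit of only these 6 libraries (adjusted p = 0.0696; 2.93e-05 to 0.0696 over 11 alternatives).

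On glucose, brlA was the tag with the greatest difference. It fell from 93.4 ± 52.8 FPKM in the wild type to 3.05 ± 1.38 in the deletion (log2 difference -4.44, SE 0.34, adjusted p = 1.44e-07). amyR fell from 222.7 ± 18.6 to 99.2 ± 41.2 (-1.23, adjusted p = 0.000231), and bgl2 rose from 7.71 ± 0.578 to 26.47 ± 6.56 (1.63, adjusted p = 1.44e-06). Of the 4 cellulase genes 0 were called over all genes or adjusted over the list alone; all were low, with cel7A-2 at 4.25 ± 2.00 against 3.21 ± 0.736 and cel6A at 11.93 ± 1.76 against 9.48 ± 1.496. limma gave cel7A-2 and cel6A an adjusted p of 0.349 and 0.173.

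Below the fold threshold on glucose, clrB was at 67.6 ± 9.39 against 38.1 ± 9.08 (log2 difference 0.83, adjusted p = 0.000489), bgl1 at 350.4 ± 2.84 against 243.6 ± 44.95 (0.54) and amy15A at 68.6 ± 9.03 against 136.3 ± 55.2 (-0.92). PDE_03922 rose from 32.19 ± 23.8 to 4124 ± 1020 (7.33, SE 0.48), and PDE_07655 reached a mean of 89.7 while listed at 0 in all 3 wild-type libraries. PDE_09239 fell from 6602 ± 715 to 4.02 ± 0.798 (-10.37, SE 0.61) and PDE_09236 from 6974 ± 584 to 5.25 ± 3.46 (-10.34, SE 0.40). Over all genes 412 rose and 515 fell, a share up of 44.4% that turned to 62.5% without the fold threshold (1843 up and 1108 down). amy15A passed the fold threshold under median-ratio scaling (-1.01) and without wild-type glucose replicate 1 (-1.11) or 2 (-1.03).

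On GlcNAc, the deletion had higher levels of cellulase genes and of the glucoamylase gene amy15A than the wild type, and the cellulase genes stayed far below their levels on bran-cellulose. cel7A-2 rose from 2.48 ± 0.549 to 9.11 ± 1.25 FPKM (log2 difference 1.54, SE 0.21, adjusted p = 1.33e-05) and cel6A from 4.67 ± 1.20 to 11.17 ± 1.33 (1.12, SE 0.17, adjusted p = 3.24e-05). amy15A rose from 47.5 ± 0.679 to 180.7 ± 50.5 (1.87) and clrB from 8.17 ± 0.479 to 20.54 ± 1.67 (1.23), both with an adjusted p of 3.51e-06. creA rose from 153.5 ± 11.2 to 312.0 ± 39.8 (1.01) while amyR fell from 21.85 ± 0.818 to 10.18 ± 1.88 (-1.04). Of the 4 cellulase genes 2 rose, over all genes and adjusted over the list alone, and all 4 passed the adjusted p at any size, with cel5B at 0.87 and cel7B at 0.61.

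xlnR on GlcNAc differed by 0.97 (23.3 ± 3.81 against 11.33 ± 0.967), bgl1 by 0.55 and brlA by -0.68 (279.4 ± 61.8 against 444.9 ± 69.5, adjusted p = 0.0907), none of them called. PDE_07475 rose from 1.78 ± 1.15 to 1107 ± 129 and PDE_06899 from 0.540 ± 0.178 to 365.7 ± 72.3. PDE_09235 fell from 4765 ± 181 to 2.99 ± 1.05 and PDE_09239 from 3358 ± 355 to 6.25 ± 6.81. The log2 difference of PDE_09239 was -9.54, and it ran from -10.39 to -8.46 when 1 library was left out. Over all genes 1401 rose and 898 fell, or 3449 and 1932 without the fold threshold. Median-ratio scaling moved the median of all genes by -0.20 and gave 1007 up and 1196 down, a share up of 45.7% against 60.9%. Under it creA (0.78) and cel6A (0.91) were no longer called, nor under quantile normalization (0.97 and 0.95).

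Single libraries also decided calls near the threshold on GlcNAc. creA was at 0.98, 0.94, 0.97 and 0.99 without deletion replicate 1, deletion replicate 2, wild-type replicate 2 and wild-type replicate 3. cel6A was at 0.95 without wild-type replicate 3, and amyR at -0.99 and -0.96 without deletion replicates 2 and 3. xlnR passed the threshold with a pseudocount of 0.1 (1.02), without deletion replicate 3 (1.09) and without wild-type replicate 2 (1.01).

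**Figure D2:**
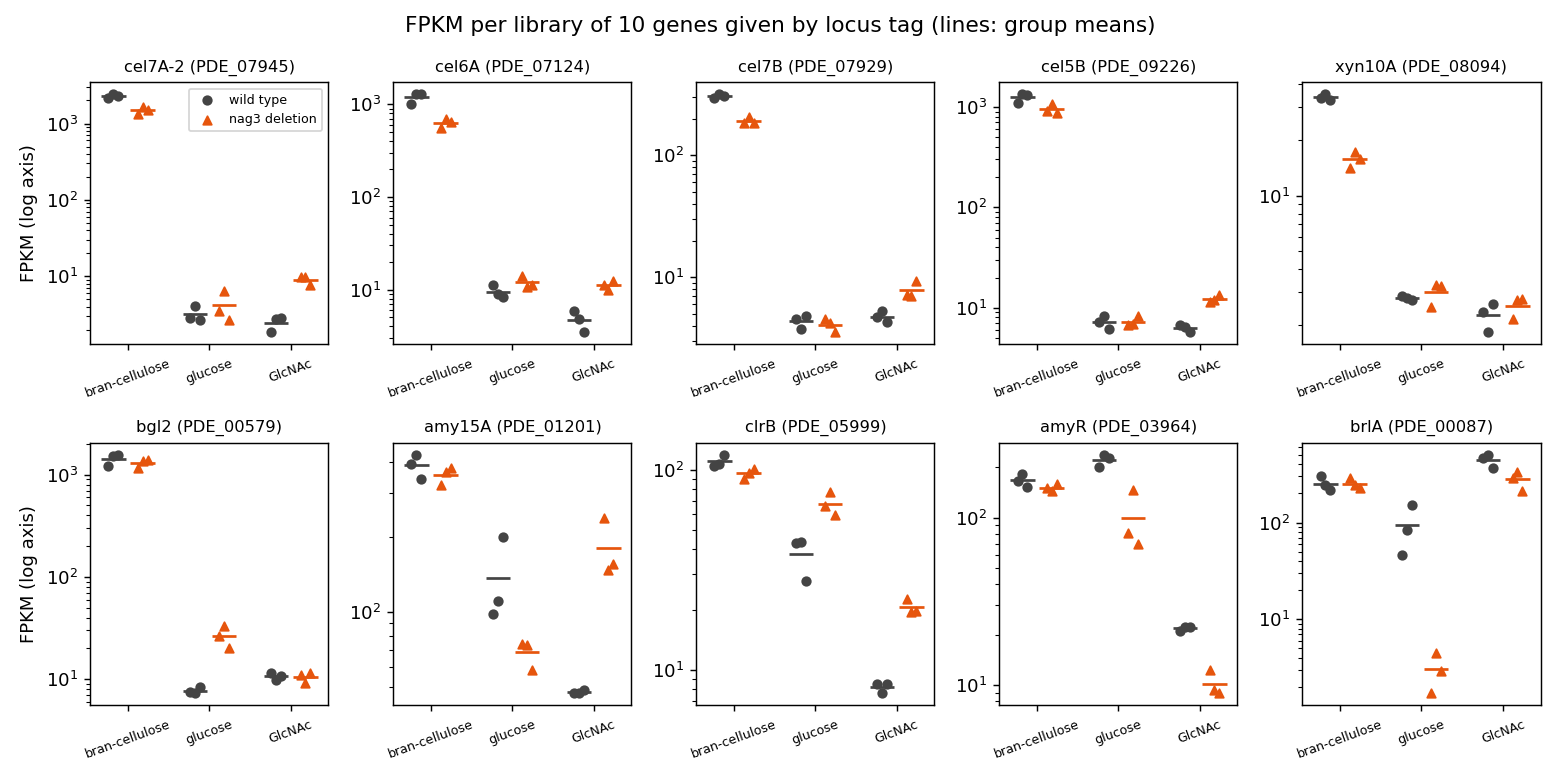
FPKM of 10 of the 13 genes given by locus tag, on log axes, in each of the 18 libraries; circles are wild type, triangles the nag3 deletion, and lines are means of 3 libraries. On glucose the brlA mean was 93.4 in the wild type and 3.05 in the deletion, and on bran-cellulose the cel7A-2 mean was 2277 and 1495.

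Genes that were called the same way in all 3 media were few, but their number is capped by bran-cellulose, where only 16 rose and 17 fell. No number for independent lists was computed for all 3 media. PDE_00965, PDE_00969, PDE_00970, PDE_08849 and PDE_08880 fell in each medium, and PDE_06209 and PDE_08882 rose in each, but for PDE_08849, PDE_06209 and PDE_08882 some of these calls ended under alternatives. On GlcNAc, PDE_00965 was at 39.4 ± 6.83 in the deletion against 4409 ± 184 FPKM, PDE_00969 at 76.8 ± 15.1 against 3820 ± 178, and PDE_00970 at 4.29 ± 0.419 against 707.6 ± 23.2. PDE_08880 was at 39.9 ± 5.27 against 1268 ± 151, and PDE_08849 was listed at 0 in all 3 deletion libraries against 263.2 ± 24.5. PDE_06209 rose on GlcNAc from 28.0 ± 10.03 to 122.0 ± 15.8. On bran-cellulose the call of PDE_06209 (2.48, adjusted p = 0.0260) ended without any 1 of the 6 libraries, with an adjusted p between 0.0553 and 0.131. In a fit of only the groups compared, calls also ended for PDE_08849 on bran-cellulose (-3.28, adjusted p = 0.0944) and for PDE_06209 on glucose (1.85, adjusted p = 0.137). The call of PDE_08882 on glucose (1.22) ended in that fit (adjusted p = 0.0983), with a pseudocount of 0.1 (adjusted p = 0.109) and without wild-type glucose replicate 1 (0.78).

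Between glucose and GlcNAc, 214 genes fell in both media against 55.1 for independent lists, and 128 rose in both against 68.8. Conversely, 52 of the genes that rose and 28 of those that fell on glucose went the opposite way on GlcNAc. For changes in opposite directions, here and below, no number for independent lists was computed. Between bran-cellulose and GlcNAc 8 fell in both against 1.82, with 2 opposite, and 4 rose in both against 2.67, with 4 opposite. Between bran-cellulose and glucose 7 rose in both against 0.786, with 0 opposite, and 5 fell in both against 1.04, with 5 opposite. These pairs share no library, but every comparison takes a gene's spread from the same fit, so the lists are not fully independent. As a mean over the 3 media, 285 genes rose and 347 fell, or 225 and 423 under median-ratio scaling (34.7% up against 45.1%, with the median of all genes moved by -0.10). Without the fold threshold most were up, 3145 against 1594. brlA fell (-1.71, SE 0.19, adjusted p = 4e-06) and no other tag was called, with amyR at -0.81, clrB at 0.62 and cel7A-2 at 0.40. PDE_09243 (3.73) and PDE_08904 (3.59) rose, and PDE_09239 (-6.59) and PDE_09235 (-6.37) fell, but none of these 4 was called on bran-cellulose, where PDE_09243 was listed at 0 in both genotypes.

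In the wild type, bran-cellulose raised the cellulase genes from low levels on glucose to those of abundant transcripts. All 4 rose, over all genes and adjusted over the list alone: cel7A-2 from 3.21 ± 0.736 to 2277 ± 128 (log2 difference 9.09, SE 0.21), cel5B from 7.18 ± 1.03 to 1255 ± 131 (7.27), cel6A from 9.48 ± 1.496 to 1192 ± 164 (6.83) and cel7B from 4.37 ± 0.569 to 307.6 ± 9.996 (5.85). bgl2 rose by a log2 difference of 7.35 and xyn10A by 3.20. clrB (1.54), amy15A (1.57) and brlA (1.57) rose as well, so that 9 of the 13 tags were higher. xlnR (0.02), creA (-0.10) and amyR (-0.41) were not called, nor was bgl1 (0.80).

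Outside the tags, PDE_07655 reached 1554 ± 245 on bran-cellulose and was listed at 0 on glucose in the wild type. PDE_01629 fell from 1896 ± 514 to 1.20 ± 0.593, and PDE_02095 fell as well (log2 difference -7.21, SE 1.48, and -8.68 to -6.47 when 1 library was left out). In all 904 genes rose and 666 fell. Median-ratio scaling moved the median of all genes by -0.16 and gave 728 and 821, a share up of 47.0% against 57.6%.

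On GlcNAc against glucose in the wild type, 3 of the 4 cellulase regulator genes fell, over all genes and adjusted over the list alone, and the cellulase genes were low in both media. amyR fell from 222.7 ± 18.6 to 21.85 ± 0.818 (-3.29, SE 0.20), clrB from 38.1 ± 9.08 to 8.17 ± 0.479 (-2.07) and creA from 458.9 ± 24.2 to 153.5 ± 11.2 (-1.57), and xlnR was not called (-0.77, adjusted p = 0.000183), while brlA rose from 93.4 ± 52.8 to 444.9 ± 69.5 (2.39, SE 0.34). amy15A fell by 1.43 and bgl1 by 1.01 on the log2 scale. Of the 4 cellulase genes 0 were called by limma, over all genes or adjusted over the list alone, with cel6A at -0.90 (adjusted p = 0.000261). Of all genes tested 5526 had an unadjusted p under 0.05, and 953 rose and 1232 fell. PDE_00965 rose from 51.74 ± 1.88 to 4409 ± 184 and PDE_02342 from 14.64 ± 25.4 to 456.2 ± 108 (6.98, SE 0.97), with 2 of its 3 glucose libraries listed at 0 and 6.06 to 8.81 when 1 library was left out. PDE_01629 (-9.42) and PDE_07933 (-8.13) fell. The bgl1 call ended under median-ratio (-0.99) and quantile scaling (-0.90), and without wild-type GlcNAc replicate 1 (-0.97) or wild-type glucose replicate 2 (-0.88). cel6A passed the threshold with a pseudocount of 0.1 (-1.02) and without wild-type GlcNAc replicate 1 (-1.04).

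The deletion also raised its cellulase genes on bran-cellulose. All 4 rose, over all genes and adjusted over the list alone, by log2 differences of 8.22 (cel7A-2), 6.85 (cel5B), 5.61 (cel6A) and 5.25 (cel7B). bgl2 rose by 5.59, xyn10A by 2.06 and amy15A by 2.37. brlA rose from 3.05 ± 1.38 to 253.2 ± 30.3 (6.02, SE 0.34), and clrB (0.51) was not called. PDE_04495 rose from 0.383 ± 0.0723 to 1547 ± 26.1, PDE_09235 rose by 9.95 (8.83 to 11.61 when 1 library was left out), and PDE_07282 (-8.40, in the same way -9.61 to -7.80) and PDE_01629 (-8.37) fell. Of the genes called on bran-cellulose in the wild type, 667 of 904 that rose and 507 of 666 that fell were called the same way in the deletion, against 112.1 and 78.7 for independent lists. In the deletion 1040 rose and 991 fell.

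On GlcNAc against glucose in the deletion, brlA rose to 279.4 ± 61.8 (6.15, SE 0.34) and amy15A to 180.7 ± 50.5 (1.36), while amyR (-3.10), clrB (-1.67) and bgl2 (-1.23) fell. bgl1 lay at the threshold as in the wild type: it was at -0.9985 and was called with a pseudocount of 0.1 (-1.002), under median-ratio (-1.13) and quantile scaling (-1.09), and without deletion GlcNAc replicate 1 (-1.03) or 3 (-1.002) or deletion glucose replicate 1 (-1.004). Of the cellulase genes, 1 was called, over all genes and adjusted over the list alone: cel7A-2, at a log2 difference of 1.00 (adjusted p = 0.000628), with cel7B at 0.79, cel5B at 0.69 and cel6A at -0.08. PDE_04495 (10.16) and PDE_04665 (9.51) rose, and PDE_03922 (-11.89) and PDE_06802 (-10.96) fell. Here 1286 genes rose and 1284 fell. Of the wild type's GlcNAc calls, 516 of 953 that rose and 677 of 1232 that fell were called the same way, against 146.1 and 188.5. The cel7A-2 call ended under median-ratio and quantile scaling (0.88 in both) and without deletion GlcNAc replicate 1 (0.95) or 2 (0.95), or deletion glucose replicate 1 (0.93) or 3 (0.79).

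The genotype difference itself differed between media for most cellulase tags. Set against GlcNAc, the difference on bran-cellulose was lower for all 4, over all genes and adjusted over the list alone: cel7A-2 by a log2 of -2.15 (SE 0.30, adjusted p = 3.27e-05), cel6A by -2.03, cel7B by -1.29 and cel5B by -1.27. Set against glucose, it was lower for cel6A (-1.22), xyn10A (-1.15), bgl2 (-1.75) and clrB (-1.03) and higher for amyR (1.09) and brlA (4.45, SE 0.48). Between GlcNAc and glucose it was higher for cel7A-2 (1.28), amy15A (2.79), xlnR (1.03), creA (1.15) and brlA (3.76), and lower for bgl2 (-1.65). Over all genes the tests called 801 genes for bran-cellulose against glucose, 2206 for GlcNAc against glucose and 2108 for bran-cellulose against GlcNAc. For the last of these 822 were up and 1286 down, or 1091 and 907 under median-ratio scaling, a share up of 54.6% against 39.0%, with a median moved by 0.20.

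Among these differences, that of clrB between bran-cellulose and glucose ended its call under median-ratio (-0.95) and quantile scaling (-0.94), and without deletion bran-cellulose replicate 1 (-0.98), deletion glucose replicate 2 (-0.92), wild-type bran-cellulose replicate 3 (-0.97) or wild-type glucose replicate 3 (-0.82). amyR ended its call without deletion glucose replicate 1 (0.99) or 3 (0.88). xlnR between GlcNAc and glucose ended its call under median-ratio (0.89) and quantile scaling (0.86), and without deletion GlcNAc replicate 1 (0.92), deletion glucose replicate 3 (0.92), wild-type GlcNAc replicate 3 (0.96) or wild-type glucose replicate 3 (0.97).

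**Figure D3:**
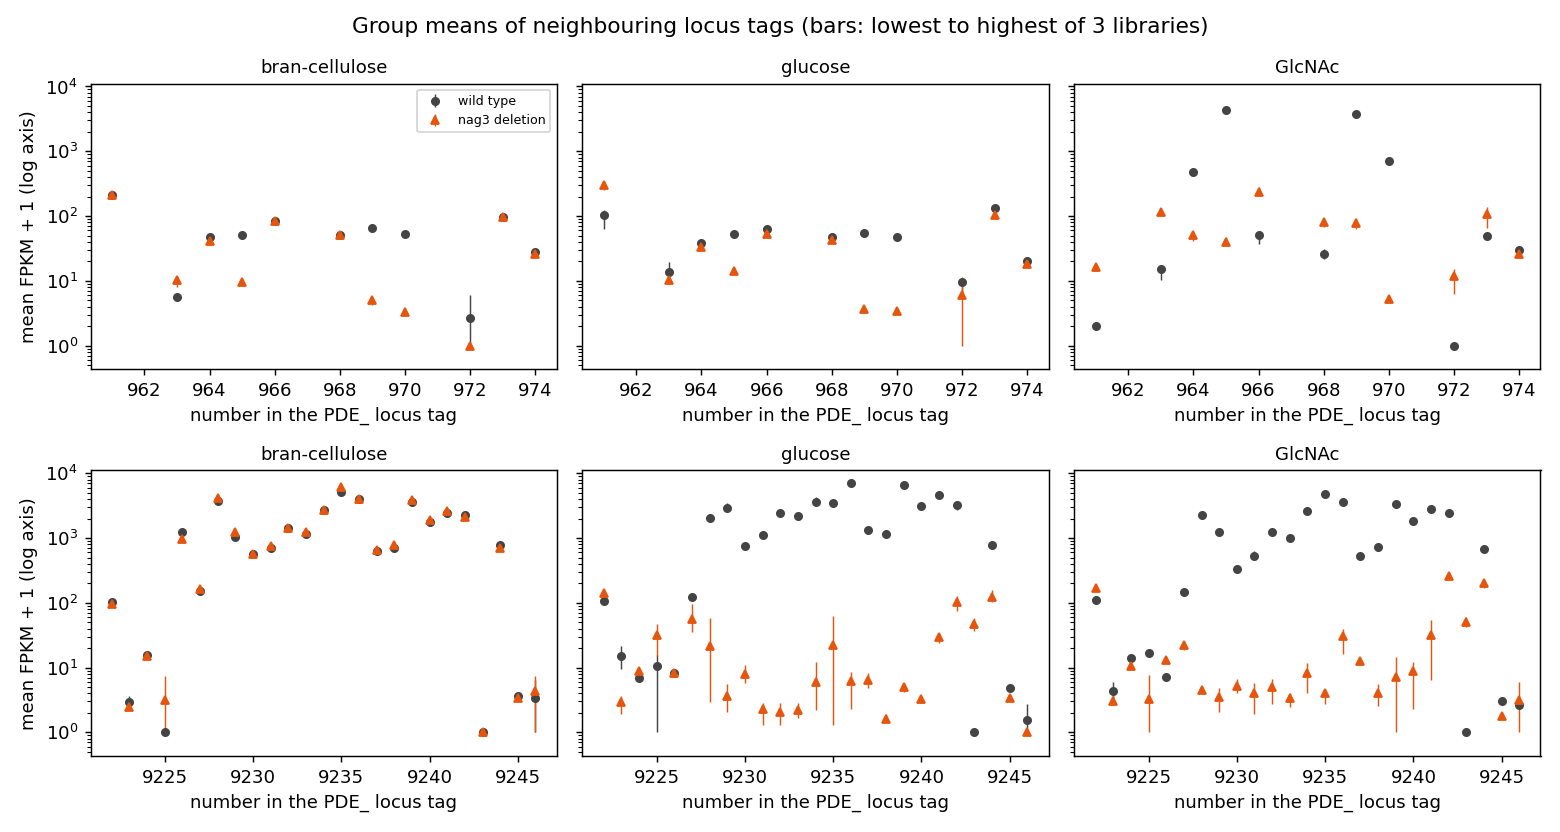
Mean FPKM + 1 on a log axis against the number in the locus tag, for PDE_00961 to PDE_00974 (top) and PDE_09222 to PDE_09246 (bottom), in each medium; circles are wild type, triangles the nag3 deletion, and bars run from the lowest to the highest of 3 libraries. PDE_00970 is lower in the deletion in all 3 media, and PDE_09239 on glucose and GlcNAc.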

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

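The tests of the 3 patterns weighed here, with their bounds, and the reading of the counts over other splits were written only after the results were seen, and some bounds were revised after a first outcome; the tests of the difference between media were fixed before the data were examined. The results in this part were picked out because the genotype difference differed between media by limma's test of that difference. The number of such genes was 801 for bran-cellulose against glucose, 2206 for GlcNAc against glucose and 2108 for bran-cellulose against GlcNAc.

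For bran-cellulose against glucose the difference of the genotype effects (log2) was -1.22 for cel6A, -1.75 for bgl2, -1.15 for xyn10A, -1.03 for clrB, 1.09 for amyR and 4.45 for brlA. By the naming rule it was 10.50 for PDE_09239, 10.36 for PDE_09236, -7.13 for PDE_03922 and -6.66 for PDE_04016.

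For GlcNAc against glucose it was 1.28 for cel7A-2, -1.65 for bgl2, 2.79 for amy15A, 1.03 for xlnR, 1.15 for creA and 3.76 for brlA. It was 11.44 for PDE_01100 (SE 3.41), 11.24 for PDE_00192, -9.72 for PDE_06802 and -8.79 for PDE_02095 (SE 2.09). PDE_01100 was listed at 0 in 2 of 3 libraries of deletion glucose and of wild-type GlcNAc, and PDE_02095 in 2 of 3 of deletion GlcNAc. When 1 library was left out, the value ran from 10.35 to 13.60 for PDE_01100 and from -11.12 to -7.63 for PDE_02095, and both stayed called.

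For bran-cellulose against GlcNAc it was -2.15 for cel7A-2, -2.03 for cel6A, -1.29 for cel7B, -1.27 for cel5B, -1.20 for xyn10A, -1.99 for amy15A and -1.43 for clrB. It was 10.53 for PDE_09235, 9.67 for PDE_09239 (8.59 to 10.52 when 1 library was left out), -8.68 for PDE_01100 (-11.31 to -6.55) and -8.43 for PDE_07475. The PDE_01100 call (adjusted p = 0.0462) ended in 13 of 17 alternatives, 9 of them fits without 1 library, over which the adjusted p ran from 0.00857 to 0.125. Its bran-cellulose libraries of both genotypes overlap, at 0, 217.5 and 31.4 FPKM in the deletion and 0, 281.3 and 194.6 in the wild type.

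The first pattern weighed is PDE_00970, low in each of the 9 deletion libraries. That PDE_00970 is the deleted gene is a candidate explanation that stays open: its highest deletion library was at 4.55 FPKM, neither under 1 as a fully removed transcript would be nor above 10, and the gene was picked for its low level. The scaling of the deposited values is argued against, since after quantile normalization the smallest of its 3 falls was still -3.70 (log2). PDE_00969 and PDE_00965, close by in tag order, fell in each medium too, but in the deletion the ratio of the highest to the lowest medium mean was 29.4 for PDE_00969 and 4.65 for PDE_00965 against 1.87 for PDE_00970. In the wild type these ratios were 70.1, 87.0 and 15.3, so a reduced response to the medium does not set PDE_00970 apart from PDE_00965.

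The second pattern is the block of 16 tags from PDE_09227 to PDE_09242, low in the deletion on glucose and GlcNAc. Loss of the block from the deletion strain is argued against by a median of 1662 FPKM on bran-cellulose in that strain, beside 1611 in the wild type. The scaling of the values is argued against by a median fall of -9.14 (log2) on glucose after quantile normalization. Spread among the wild-type glucose libraries is argued against by a median ratio of 1.23 between the highest and lowest of those libraries. A response to genotype that depends on the carbon source may remain, as a hypothesis found and tested on the same data. For the 23 tags from PDE_00789 to PDE_00811, also low in the deletion on glucose, that ratio was 6.02, and spread among those libraries cannot be told apart from genotype as part of the cause, since the wild-type libraries vary but do not reach the deletion's level.

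The third pattern is the small number of genes called on bran-cellulose (33, or 66 with array weights) against glucose (927) and GlcNAc (2299). Larger spread within the bran-cellulose libraries is argued against, as the larger of its median SDs was 0.703 of the smaller glucose one. The test takes a gene's spread from all 6 groups, so this ratio does not cover the shared spread. In limma fits of only the groups compared, 36 genes passed the adjusted p at any size on bran-cellulose. The same fits gave 1452 on glucose and 5163 on GlcNAc, so the order of the counts did not rest on the shared spread. A mislabelled sample among the 6 bran-cellulose libraries is argued against, as no other split of them called more than 3 genes. The main axis of spread among the 3 wild-type glucose libraries correlated with the genotype difference on glucose at an absolute r of 0.401 across 8390 genes, which are not independent replicates (0.184 for the deletion glucose libraries). Whether part of the glucose difference follows that spread stays open, while on GlcNAc such spread is argued against as the whole cause by an absolute r of 0.103 in the wild type and 0.0954 in the deletion.

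Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05; in each of these comparisons the count was 1 of 10, the real split. On bran-cellulose the real count was 33 and the highest other 3, on glucose 927 and 5, and on GlcNAc 2299 and 1. For bran-cellulose against glucose they were 1570 and 1 in the wild type and 2031 and 1 in the deletion, and for GlcNAc against glucose 2185 and 1, and 2570 and 61. For genotype over the 3 media 100 of 4000 possible splits were counted. Only the real one called 632 genes or more, and 419 was the highest other. The 66 splits that keep no medium's genotypes apart called at most 1 gene. A random grouping of these libraries is argued against. Chance differences between cultures cannot be excluded, since the replicates may be technical.

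For the 3 tests of a difference between media chance cannot be excluded by this count. Of 100 splits 7 called at least 801 genes (highest other 820), 5 called at least 2206 (highest other 2502) and 11 called at least 2108 (highest other 2405). All of the other splits that reached these counts keep the genotypes apart in 1 of the media, so they hold a real genotype difference. Splits that keep neither medium's genotypes apart, 77, 78 and 76 in number, called at most 4, 1 and 1 genes.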

How the results depend on the processing

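Counts of called genes kept within 1.5 times of the reported value in 176 of 181 alternatives. The 5 others were array weights on bran-cellulose (66 genes against 33) and the removal of the fold threshold for deletion vs wild type, with 60 genes on bran-cellulose, 2951 on glucose, 5381 on GlcNAc and 4739 over the 3 media, where the looser threshold is the cause; for array weights the cause was not tested. Without the fold threshold the split was 1843 up and 1108 down on glucose, and 3145 and 1594 over the 3 media. Leaving out each library in turn gave 26 to 33 genes on bran-cellulose, 786 to 1020 on glucose, 2234 to 2362 on GlcNAc and 570 to 694 over the 3 media. It gave 1404 to 1751 and 1986 to 2397 for bran-cellulose and GlcNAc against glucose in the wild type, 1917 to 2179 and 2508 to 2654 in the deletion, and 704 to 932, 2143 to 2341 and 2029 to 2153 for the differences between media (bran-cellulose against glucose, GlcNAc against glucose, bran-cellulose against GlcNAc).

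Scaling moved the median of all genes by over 0.1 (log2) in several comparisons: median-ratio scaling also by -0.12 for GlcNAc against glucose in the deletion and by -0.14 for the GlcNAc against glucose difference, beside those given with the results. Quantile normalization moved it by -0.16 for genotype on GlcNAc, by -0.14 and -0.11 for bran-cellulose against glucose in the wild type and the deletion, and by -0.15 and 0.15 for the differences GlcNAc against glucose and bran-cellulose against GlcNAc. TPM moved it by 0.10 for genotype on GlcNAc, by -0.14 for GlcNAc against glucose in the wild type and by 0.13 for the GlcNAc against glucose difference, opposite in sign to the other scalings. Over 205 results for single genes and 2748 alternatives, 2660 kept their status (called or not), 62 lost the call and 26 gained one. In 0 of them the sign changed with a call in either fit. A change of sign without a call was not counted. With the replicate block, the count was 32 on bran-cellulose, 924 on glucose and 2304 on GlcNAc, and 2 single-gene calls were lost, PDE_06209 on bran-cellulose (adjusted p = 0.0545) and PDE_01100 between bran-cellulose and GlcNAc (0.0525). Same-numbered samples had a correlation of deviations over 0.1 in 6 of 45 pairs. The own number gave the best correlation in 28 of 90 cases. No pairing by number was seen, which does not exclude that samples were handled in numbered sets. Other settings of the gene list tests were not run, as no list reached 5 members. Without counts, depth sets no stated limit; 0 values are identifiers listed at 0.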

Other observations

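The tests and locus-tag ranges in this part were chosen after the values were seen. Several long stretches of consecutive kept locus tags changed together. All 16 tags from PDE_09227 to PDE_09242 fell in the deletion on glucose (median log2 difference -9.31) and on GlcNAc (-7.77), and none was called on bran-cellulose (0.10). Their median level in the wild type was 1611 FPKM on bran-cellulose, 2677 on glucose and 1536 on GlcNAc, and in the deletion 1662, 5.13 and 5.24. Next to them PDE_09243 went the other way on glucose and GlcNAc, from 0 to 46.0 and 50.3 FPKM, and was listed at 0 in both genotypes on bran-cellulose. The tag after that, PDE_09244, was lower in the deletion on glucose (123.6 against 766.6 FPKM) and on GlcNAc (197.8 against 666.3). On bran-cellulose PDE_09244 was at 705.5 in the deletion against 787.7 in the wild type.

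From PDE_00789 to PDE_00811, 22 of 23 tags fell in the deletion on glucose (median -5.14) and 19 on GlcNAc (-1.93). In the wild type the same tags were higher on GlcNAc than on glucose in 23 of 23 cases, with a median of 2.70. Of the 14 tags from PDE_09999 to PDE_10012, 12 fell in the deletion on glucose (median -4.19), while on GlcNAc 4 fell and 1 rose (-0.72) and on bran-cellulose 0 were called (-0.13). In the wild type 14 were higher on bran-cellulose than on glucose (2.11). The median ratio between the highest and lowest wild-type glucose library was 5.26 for these 14 tags.

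Neighbouring tags were called the same way 179 times in the glucose comparison of genotypes, where 10000 shuffles of the tag order gave at most 79, and 536 times in the GlcNAc comparison, where they gave at most 382. The permutation p was 1e-04 in both, the smallest that these shuffles can give, and it was the same in every other comparison. For genotype on bran-cellulose the count was 3 against at most 2. In the wild type it was 327 against at most 197 for bran-cellulose against glucose, and 513 against at most 344 for GlcNAc against glucose. Neighbours called the same way are thus not particular to the deletion. A random order of called genes is argued against, and shared regulation of neighbours may account for part of it; whether these stretches are gene clusters of one pathway was not tested.

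PDE_09832 held the highest share of the FPKM sum of any gene in every library except those of the deletion on glucose. Its share on GlcNAc was 13.7 ± 0.883% in the deletion and 9.20 ± 0.847% in the wild type. On bran-cellulose it was 7.17 ± 0.454% in the deletion and 8.05 ± 0.331% in the wild type, and in the wild type on glucose 3.09 ± 0.590%.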
